A study of Mus musculus with 9 samples.

How the data were processed

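The samples were 9 ChIP-seq libraries of haemogenic endothelium derived in culture from mouse ES cells of 3 lines (Bry, Hd1_loxlox and Hd2lox). In each line chromatin was precipitated with an Hdac1 antibody (Diagenode) or an Hdac2 antibody (abcam), and an input library was made. ChIP used a commercial kit, per the labels' protocols. Per the submitters' processing notes, the tools included bcl2fastq, Bowtie2 2.2.9 for alignment, SAMtools 1.3.1 and MACS2 2.1.1.20160309 for peak calling, and the build was mm10. The calling threshold, the MACS2 mode and whether the input libraries served as controls are not given in the sources used here. The deposited values are positions: each of the 6 ChIP libraries had 1 list with the chromosome, start and end of each peak, deposited by the authors for that library alone, with no score, summit or count. Peaks were therefore called per library. The 3 input libraries were not analysed here, so the background in input could not be set beside the peaks. If the Hdac1 and Hdac2 libraries of a line were called against the same input, they share its local errors, which can add common regions, and this cannot be simulated from positions.

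All 46202 peaks lay on chromosomes 1 to 19, X and Y, and positions are given 1-based on mm10. Genes came from a RefSeq table of GRCm38, the same assembly, with 21887 protein-coding genes and 49943 genes in all on these chromosomes. The table gives the outer ends of each gene but no strand and no internal promoters. The planned windows around transcription start sites were therefore replaced by windows of 1000 bp either side of both annotated ends, called gene ends in the report, and a gene was counted as bound in a library when a peak overlapped either window by 1 bp or more. A peak at a gene end can lie at the start or at the stop of the gene, or belong to a neighbour, and promoters inside a gene are missed. With no genome sequence in use, the planned motif, repeat and promoter CpG analyses were not run. With no score per peak, planned rankings by the authors' score used the percentile of peak width within the list instead. The lists are not in positional order, and order correlated with width across peaks (Spearman rho of -0.787 for Hdac1 and -0.735 for Hdac2 in Bry, -0.79 and -0.355 in Hd1_loxlox, and -0.327 and -0.547 in Hd2lox). Peaks are not independent replicates.

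The lists of the 6 libraries were merged into regions where they overlapped by 1 bp or more, and a region was present in a list when a peak of that list fell in it. Similarity of 2 lists was the Jaccard index of present regions. Shares at gene ends have 95% Wilson intervals, which cover counting error only. Expected values came from 100 placements of the peaks of each list at random on the same chromosome with the same widths, and, for shared regions, from 100 placements that sent peaks at gene ends to random gene ends of the same chromosome. Read depth is unknown, so a gene without a peak may have had too few reads.

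The 3 lines were the replicates of each antibody, 3 against 3. Numbers, widths and shares were compared with exact two-sided permutation tests of the difference of means, for which the smallest p is 0.1, so no such comparison can pass a threshold of 0.05. The Hdac1 and Hdac2 libraries of a line are paired, since same-numbered samples come from the same cell line by their labels, and a sign-flip permutation test by line (smallest p 0.25) was the paired alternative. Jaccard indices within and between antibodies, or within and between lines, were compared by exact one-sided permutation over 10 and 15 arrangements. The labels do not say that the lines were cultured or processed in separate experiments, so p-values measure the spread between these libraries, which may be technical in part.

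Gene lists were fixed before the data were examined: TGF-beta, BMP and Notch signalling, haematopoietic transcription factors, endothelial, blood cell, cardiac with smooth muscle and mesenchymal, pluripotency, and neural with endoderm genes, subunits of Hdac1 and Hdac2 complexes, cell cycle, immediate early, ribosomal protein, replication-dependent histone, oxidative phosphorylation, translation initiation factor, proteasome, Hox and Zfp genes, and olfactory receptors as a negative control. The 40 names of the TGF-beta list gave 39 genes and the 35 of the complexes gave 34, since Ctgf and Elmsan1 are older names of genes also listed as Ccn2 and Mideas. Hoxa9 and Hoxb4 are in both the haematopoietic and the Hox list. Each list was tested with Fisher's exact test (two-sided) among genes bound in at least 2 of 3 lines against all other protein-coding genes, with Benjamini-Hochberg adjustment over 40 tests (20 lists, 2 antibodies) at 0.05. Odds ratios have 0.5 added to each cell. For sets of genes specific to a line the background was the genes bound in any list, with adjustment over 80 tests. Enrichment per library was compared between antibodies by exact permutation of log2 odds ratios, adjusted over the 20 lists. Background genes were not matched for promoter CpG content or expression.

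Named genes followed a rule written before the data were examined: the Hdac1 and Hdac2 genes, up to 15 TGF-beta genes bound in at least 2 lines for either antibody, up to 4 genes of every other list by the number of lists, the 10 genes per antibody bound in all 3 lines with the highest lowest width percentile, and up to 8 genes bound in all lines of an antibody or in both lists of a line and nowhere else. Unbound genes, the line-specific Hox genes, Tgfb2, Tgfb3, Runx1, Erg, Spi1 and Lmo2 were named after their values were seen. Some genes that the rule selects are not reported here.

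Alternatives were leaving out each line, other windows (500, 2500 and 5000 bp), gene ends of all annotated genes, 50% reciprocal overlap or a gap of up to 500 bp for shared regions, and a peak in all 3 lines. Alternatives chosen after seeing the data were the wider 50% of each list, lists shortened by width to the length of the shortest, the first 50% in file order, leaving out the Hd1_loxlox Hdac2 list, and leaving out chromosomes 8, 11, 16, X and Y. The code was tested on simulated data: 1000 of 1000 planted shared regions were found, and for the gene list test, with 30 genes per list among 21887, 17 of 20 lists simulated with an odds ratio of 4 were recovered and 0 of 20 lists without enrichment were called. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.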

Results

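Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the histone deacetylases Hdac1 and Hdac2 sat on the genome of mouse haemogenic endothelium, the endothelial cells that give rise to the first blood cells. The cells were differentiated in culture from embryonic stem (ES) cells of 3 lines of the C57BL/6 strain, labelled Bry, Hd1_loxlox and Hd2lox, and the labels record no treatment. Each line gave 1 Hdac1 library, 1 Hdac2 library and 1 input library, so each antibody had n = 3 lines and each combination of line and antibody had 1 library. Bry was used at passage 16 to 19 and the other lines at passage 25 to 30. The data analysed here were 6 lists of peak positions on the mm10 build, 46202 peaks in total, and the 3 input libraries were not analysed here. The lists held 7671 peaks for Hdac1 and 9279 for Hdac2 in Bry, 7490 and 5161 in Hd1_loxlox, and 7519 and 9082 in Hd2lox. The lists carry no read counts or peak heights, so read depth is unknown and all comparisons rest on the presence and width of peaks.

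The first comparison asked how Hdac1 and Hdac2 peaks were distributed over genes. Most Hdac1 peaks lay at the ends of protein-coding genes in all 3 lines. Most Hdac2 peaks did so in Bry, but the Hdac2 share was lower in Hd2lox and lowest in Hd1_loxlox. In Bry, 77.5% of Hdac1 peaks (Wilson 95% interval 76.5 to 78.4%) and 70.8% of Hdac2 peaks (69.9 to 71.7%) lay within 1000 bp of an annotated end of a protein-coding gene. In Hd2lox the shares were 63.9% (62.8 to 64.9%) and 30.1% (29.2 to 31.0%). In Hd1_loxlox they were 79.7% (78.8 to 80.6%) for Hdac1 and 10.3% (9.55 to 11.2%) for Hdac2, and 43.5% of that Hdac2 list lay outside genes. Random placement of the same peaks on their chromosomes gave between 4.41% and 5.66%, and the Hd1_loxlox Hdac2 share was 2.12 times its random mean while the other 5 lists lay between 6.82 and 14.1 times theirs. The intervals cover counting error only.

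Across the 3 lines the share at gene ends was 73.7% ± 8.57 for Hdac1 and 37.1% ± 30.8 for Hdac2 (SD, n = 3 each; exact two-sided permutation p = 0.2). The share of Hdac2 minus that of Hdac1 was -6.68 percentage points in Bry, -69.3 in Hd1_loxlox and -33.8 in Hd2lox (paired sign-flip permutation p = 0.25, the smallest possible). The difference of the means, Hdac1 minus Hdac2, was 36.6 points, against 20.2 without Hd1_loxlox and 23.2 without its Hdac2 list alone. Hdac1 peaks had a higher mean of the list medians of width, 1432 ± 51.3 bp against 1077 ± 244.7 bp (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). The gap was small in Bry, with medians of 1375 bp for Hdac1 and 1310 bp for Hdac2. It was larger in Hd1_loxlox (1475 and 1099 bp) and Hd2lox (1445 and 822 bp). The number of peaks, 7560.0 ± 97.2 for Hdac1 and 7841 ± 2323 for Hdac2 (SD, n = 3), differed by less than the spread between lines (exact permutation p = 1), as did the covered length, 11.8 ± 0.257 Mb against 8.99 ± 3.96 Mb (SD, n = 3; exact permutation p = 0.4). Genes with a peak at an end numbered 6989 for Hdac1 and 7532 for Hdac2 in Bry, 6934 and 594 in Hd1_loxlox, and 5315 and 2946 in Hd2lox, or 6413 ± 951.0 against 3691 ± 3528 (SD, n = 3; exact permutation p = 0.4). Without the Hd1_loxlox Hdac2 list, the mean number of Hdac1 peaks minus that of Hdac2 was -1620.5 (exact permutation p = 0.1, the smallest possible with 3 lists against 2).

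**Figure D1:**
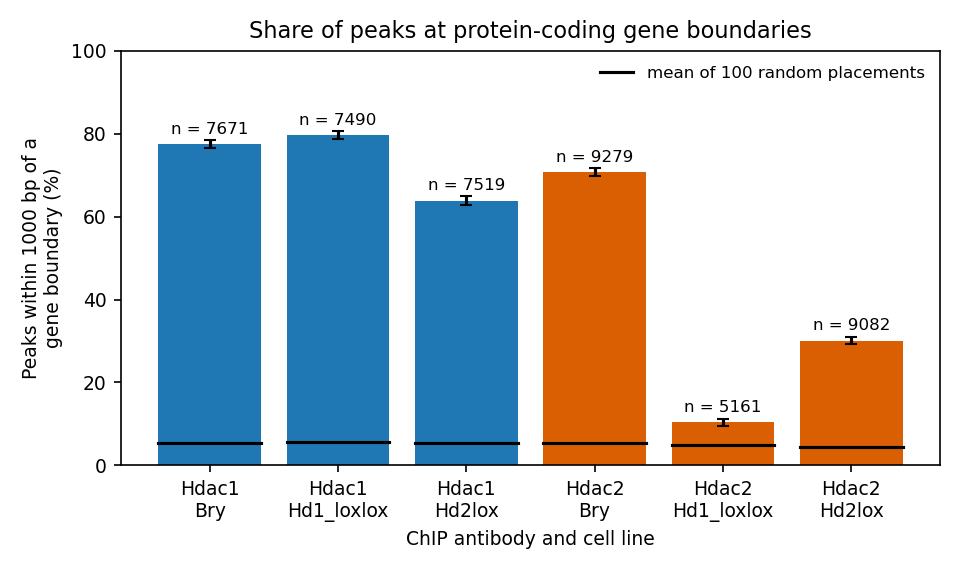
Share of peaks (percent, vertical axis) within 1000 bp of either annotated end of a protein-coding gene in each of the 6 peak lists, with 95% Wilson intervals and the mean of 100 random placements as a line. The Hdac2 list of Hd1_loxlox, at 10.3%, lies closest to its random level, and the Hdac1 list of Hd1_loxlox, at 79.7%, is the highest.

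The next comparison asked which regions recurred. Hdac1 occupied a large common set of gene ends in the 3 lines, and 66.1% of the Bry Hdac2 peaks overlapped a Bry Hdac1 peak. Merging the 6 lists gave 24761 regions, of which 3214 were in all 3 Hdac1 lists and 132 in all 3 Hdac2 lists. Of the common Hdac1 regions 86.8% lay at gene ends, as did 80.3% of the common Hdac2 regions. Random placements that kept each list's share at gene ends gave at most 202 and 22 such regions in 100 draws. Without the Hd1_loxlox Hdac2 list, 2283 regions were in both remaining Hdac2 lists. A further 15440 regions were in 1 list only, 4721 of them in the Hd1_loxlox Hdac2 list and 5726 in the Hd2lox Hdac2 list, and of these 6.27% and 3.39% lay at gene ends. Random placement put 4.88% and 4.41% of the peaks of these lists at gene ends.

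The most similar lists were the Hdac1 lists of Bry and Hd1_loxlox, with a Jaccard index (shared regions over all regions of the pair) of 0.584, followed by Hdac1 and Hdac2 within Bry at 0.566 and Bry Hdac2 with Hd1_loxlox Hdac1 at 0.528. Hd2lox Hdac1 reached 0.327 to 0.356 with these 3 lists and 0.244 with Hd2lox Hdac2. Every pair with the Hd1_loxlox Hdac2 list was at 0.0137 to 0.0264, although each exceeded its own highest matched random value, the largest of which was 0.0142. Lists of the same antibody and of different antibodies had mean Jaccard indices of 0.241 and 0.225 (difference 0.0162, one-sided exact permutation p = 0.2 over 10 arrangements). The difference was -0.0851 without Hd1_loxlox. Lists of the same line had a mean of 0.279 against 0.220 for lists of different lines (difference 0.0594, one-sided exact permutation p = 0.333 over 15 arrangements). That difference was 0.00185 without Bry, 0.00706 without Hd2lox, 0.170 without Hd1_loxlox and 0.0856 without its Hdac2 list alone. With so few arrangements neither comparison can reach a p of 0.05.

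**Figure D2:**
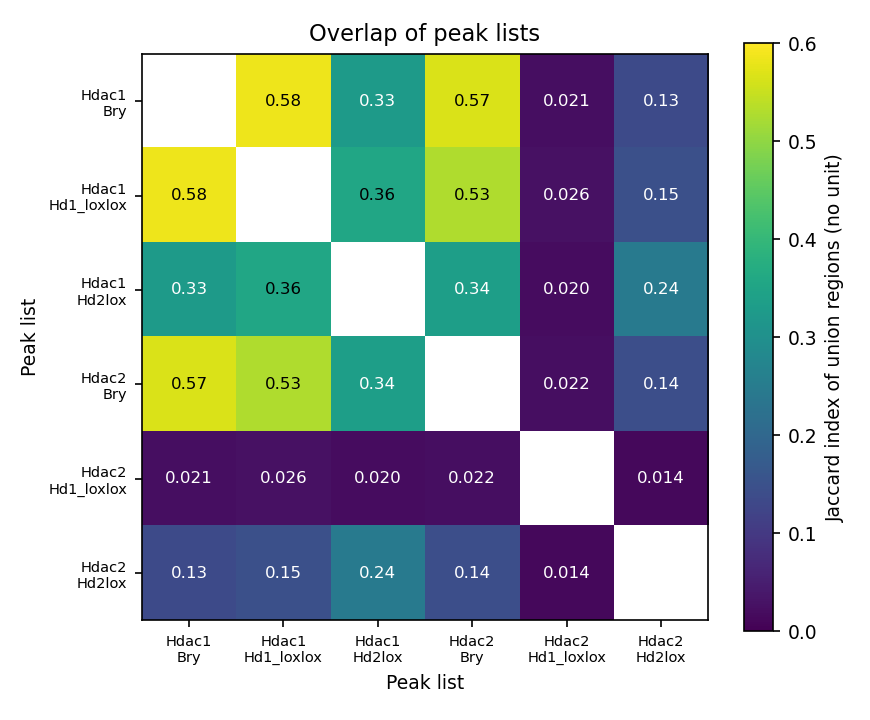
Jaccard index of every pair of the 6 peak lists (shared regions over all regions of the pair, 0 to 1). The Bry lists and the Hd1_loxlox Hdac1 list form the most similar trio, at 0.528 to 0.584, and every pair with the Hd1_loxlox Hdac2 list is at 0.0264 or below.

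Few sites were in all 3 lists of an antibody and in none of the other. The only region in all 3 Hdac2 lists and no Hdac1 list lay on chromosome 11 at 76997212-76999138, over the lower end of Slc6a4 (76998597-77032343), the serotonin transporter gene. The Hd1_loxlox peak (76997463-76998028) and the Hd2lox peak (76998171-76999066) did not overlap and were joined only by the Bry peak. The Hd1_loxlox peak ended before the gene, so no single site was common to the 3 lists. The 135 regions in all 3 Hdac1 lists and no Hdac2 list lay at gene ends in 90.4% of cases. Genes with an end peak in all 3 Hdac1 lists and no Hdac2 list included Klf7, a Krüppel-like transcription factor, Psme4, a proteasome activator, Dazap2, Adamts3, a procollagen peptidase, and Gnai2, an inhibitory G protein subunit. The neighbouring genes Atp6v1a, a subunit of the vacuolar proton pump, and Naa50, an N-terminal acetyltransferase, shared 1 such peak, and the Isg15 peaks lay outside the annotated gene. Matched random placements gave a mean of 100.1 and at most 122 Hdac1-only regions, and a mean of 6.43 Hdac2-only regions. Those placements were independent between lists and gave a mean of 163.5 regions in all 3 Hdac1 lists, against 3214 observed. Most regions common by placement were thus Hdac1-only, but few of those observed were, so the count of 135 cannot be read as an excess. Without Bry there were 1759 Hdac1-only and 32 Hdac2-only regions, without Hd2lox 725 and 27, without Hd1_loxlox 198 and 12, and without the Hd1_loxlox Hdac2 list alone 138 and 8.

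Target genes were then compared between the antibodies. A peak at a gene end in at least 2 of 3 lines was found at 6606 genes for Hdac1 and at 2314 for Hdac2, and 2040 genes (88.2% of the Hdac2 genes) had both. Independent lists would have shared 698 genes, which gives an odds ratio of 24.5. In all 3 lines the numbers were 3185, 132 and 98, with 19.2 shared genes expected and an odds ratio of 17.4 (Fisher's exact test p = 5.99e-54). Without the Hd1_loxlox Hdac2 list, 1464 genes were shared by all remaining lists, and without the line Hd1_loxlox 1642 were. Within Hd2lox 93.1% of the Hdac2 genes were Hdac1 genes, within Bry 76.4%, and within Hd1_loxlox 52.9%. These tests describe the lists, since neighbouring genes share peaks and genes are not independent replicates, and shared input libraries, where used in peak calling, would add common regions.

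The genes whose Hdac1 peaks were among the widest of the list in each of the 3 lines were Smad7, an inhibitory SMAD of TGF-beta signalling, Bahcc1, Yy1, a zinc finger regulator, Igf1r, the type 1 insulin-like growth factor receptor, Ing1, a histone reader of the Sin3 deacetylase complex, Zfp423, Sall1, Irf2bp2, Vasp, an actin regulator, and Sh2b3, an adaptor that restrains cytokine signalling. The Bahcc1 peak reached 10123 bp in Hd1_loxlox, the widest Hdac1 peak of that line. The corresponding Hdac2 genes, which had to have a peak in the Hd1_loxlox Hdac2 list too, were Acvr2b, an activin type II receptor, Kmt2a, a histone H3 lysine methyltransferase needed for blood stem cells, Plxnc1, Klhl21, Nol4l, Dact2, Ube2q2, Adamtsl3, Phyhipl and Ankrd34b. All of these Hdac2 genes had Hdac1 peaks too, in all 3 lines except Phyhipl (not in Bry) and Ankrd34b (not in Hd1_loxlox).

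The series title places Hdac1 and Hdac2 in the control of TGF-beta, and genes of this pathway carried each protein more often than other genes. Of 39 TGF-beta signalling genes, 22 (56.4%) had an Hdac1 peak at an end in at least 2 lines, against 30.1% of other protein-coding genes (odds ratio 2.98, Fisher's exact test adjusted p = 0.00218 over 40 tests). For Hdac2 the numbers were 10 genes (25.6%) against 10.5% (odds ratio 3.02, Fisher's exact test adjusted p = 0.0154). Hdac1 odds ratios were higher for ribosomal protein (3.03), cell cycle (3.30), translation initiation factor (4.47) and immediate early genes (9.53). They were lower for proteasome (2.44) and oxidative phosphorylation genes (1.11). The Hdac1 enrichment is therefore not particular to this pathway. By library, Hdac1 was at 24 of these genes in Bry, 21 in Hd1_loxlox and 23 in Hd2lox, and Hdac2 was at 27, 1 and 10. No difference between the antibodies in this enrichment was detected, with a difference of 0.50 between the mean log2 odds ratios (SD 0.41 for Hdac1 and 0.80 for Hdac2, n = 3; exact permutation p = 0.4 where 0.1 is the smallest possible, adjusted p = 0.769). The Hdac1 call held without any of the lines. Without Bry or Hd2lox an Hdac2 gene had to be in the Hd1_loxlox Hdac2 list, which held 1 of the 39, so the loss of the call there (log2 odds ratios of 2.41 and 1.42 against 1.59, Fisher's exact test adjusted p of 0.498 and 0.617) does not measure dependence on those lines. Without that list the Hdac2 call held (log2 odds ratio 1.75, Fisher's exact test adjusted p = 0.00824).

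The bound TGF-beta genes spanned the pathway from ligand to nucleus. Acvr2b was in all 6 lists. The 5 lists other than Hdac2 of Hd1_loxlox held the ligand gene Tgfb1, the type I receptor Tgfbr1, Ltbp1, which holds the latent ligand in the matrix, Fkbp1a, a protein that binds the type I receptor, the ubiquitin ligase Smurf2 and Smad7. The signal transducers Smad3 and Smad4, the co-repressors Ski, Skil and Tgif2, and the receptor Acvr1b were in all 3 Hdac1 lists and in Hdac2 of Bry. Pmepa1, a feedback inhibitor, and Zfyve9, which presents SMADs to the receptor, were in 2 lists of each antibody. No list had a peak at an end of Eng or Acvrl1, the endothelial TGF-beta receptor genes, or of Tgfb2 and Tgfb3, the other ligands, although Tgfb2 had a peak inside the gene in 2 Hdac1 lists, and 9 of the 39 genes had no end peak.

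At Smad7 (chromosome 18, 75367365-75395935) the Hdac1 peak covered the lower end of the gene in each line, at 75366116-75371521 in Bry, 75366034-75372820 in Hd1_loxlox and 75366731-75372108 in Hd2lox. These peaks also overlapped the end of the neighbouring gene Gm20544 (75358639-75367088). The Hdac2 peak of Bry lay at 75366108-75370076, and Hd2lox had 3 narrower Hdac2 peaks between 75367059 and 75371058. The same 5 lists had a further peak at lower coordinates, at 75342283-75343966 for Hdac1 in Hd2lox. The Hd1_loxlox Hdac2 list had no peak at either place, and its only peak nearby was at 75328130-75329089.

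**Figure D3:**
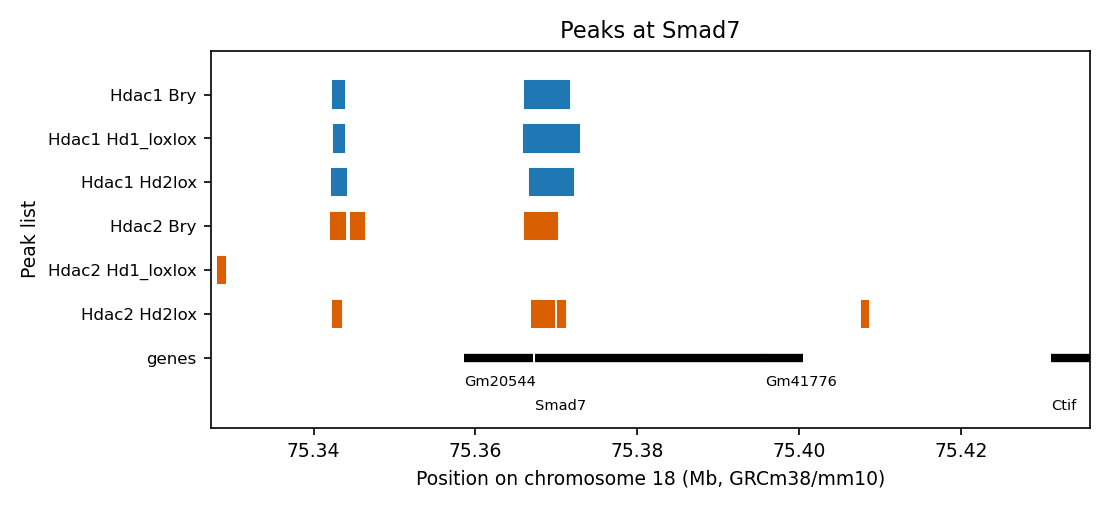
Map of peaks around Smad7 on chromosome 18 (mm10 position in Mb, horizontal axis), with a track for each of the 6 lists (Hdac1 blue, Hdac2 orange) and genes in black. A peak over the lower end of Smad7 is present in the same 5 lists, and is 5378 to 6787 bp wide for Hdac1.

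Of the other lists of signalling, blood and vessel genes some passed the test and others did not, and the lists were not compared with each other. Notch signalling genes had Hdac1 at 14 of 18 members (odds ratio 7.47, Fisher's exact test adjusted p = 0.000169) and Hdac2 at 11 (odds ratio 13.0, adjusted p = 2.26e-06), with the receptor Notch1, the target Hes1, the coactivator Maml1 and the ligand Jag2 in 5 lists each. BMP signalling genes had Hdac1 at 16 of 21 (odds ratio 6.95, Fisher's exact test adjusted p = 8.04e-05) and Hdac2 at 6 (odds ratio 3.55, adjusted p = 0.0414), with Bmp7 in all 6 lists and Bmp2, Smad1 and the inhibitor Smad6 in 5. Haematopoietic transcription factors had Hdac1 at 17 of 30 (odds ratio 3.004, Fisher's exact test adjusted p = 0.00682) and Hdac2 at 7 (odds ratio 2.70, adjusted p = 0.0674), with Kmt2a in 6 lists and Cebpa, Zfpm1 and Hhex in 5. Runx1, the master regulator of the endothelial-to-blood switch, Erg, Spi1 and Lmo2 had no peak at an outer end in any list. Peaks elsewhere in the gene were present for Runx1 and Lmo2 in 3 Hdac1 lists and 1 Hdac2 list each, for Erg in 3 and 2, and for Spi1 in 1 Hdac2 list. Neither endothelial genes (Hdac1 16 of 34, Fisher's exact test adjusted p = 0.0746, Hdac2 5, adjusted p = 0.552), among them Elk3, Ets2, Efnb2 and Rasip1 in 5 lists, nor blood cell genes (Hdac1 4 of 26, adjusted p = 0.198, Hdac2 0, adjusted p = 0.164), among them Kit, Itga2b, Itgb3 and Gp1bb in 3 lists, passed the test. In Bry alone Hdac2 was at 20 of the 34 endothelial genes and 20 of the 30 haematopoietic factors (Fisher's exact test adjusted p of 0.00957 and 0.00113 over 120 tests). Blood cell genes were depleted there for Hdac2 (3 of 26, Fisher's exact test adjusted p = 0.0300) and in Hd2lox for Hdac1 (1 of 26, adjusted p = 0.0262). For haematopoietic factors with Hdac1 the log2 odds ratio of 1.59 became 1.299 without Bry and 1.15 without Hd1_loxlox (Fisher's exact test adjusted p of 0.102 and 0.159). Both settings required a peak in the Hd2lox Hdac1 list, which held 13 of the 30, so they do not measure dependence on the omitted line. By library these factors passed for Hdac1 in Bry and in Hd1_loxlox but not in Hd2lox. The Hd1_loxlox Hdac2 list, required when Bry or Hd2lox was left out, held 1 of the 21 BMP and 2 of the 18 Notch genes, so the loss of these Hdac2 calls there followed from that list. Without that list both held (Fisher's exact test adjusted p of 0.0266 and 7.45e-05).

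Hdac1 was also at the genes of its own complexes. Of 34 subunit genes of Hdac1 and Hdac2 complexes, 29 (85.3%) had Hdac1 peaks in at least 2 lines and 18 in all 3 (odds ratio 12.5, Fisher's exact test adjusted p = 5.22e-10) and 8 had Hdac2 peaks (odds ratio 2.72, adjusted p = 0.048), among them Ing1, Ing2, Rcor2 and Rcor3 in 5 lists each. The mean log2 odds ratio was 3.09 ± 0.54 for Hdac1 and 1.02 ± 1.71 for Hdac2 (SD, n = 3; exact permutation p = 0.1, the smallest possible, adjusted p = 0.75). The Hd1_loxlox Hdac2 list held 0 of the 34, and without it the Hdac2 call held (Fisher's exact test adjusted p = 0.0282). The Hdac2 gene (chromosome 10, 36974297-37001889) had a peak over its lower end in all 3 Hdac1 lists, at 36973699-36976000 in Bry, and in the Bry Hdac2 list. The Hdac1 gene (chromosome 4, 129516104-129542646) had a peak over its upper end at 129541682-129542922 in the Hd1_loxlox Hdac1 list, and a Bry Hdac2 peak at 129513200-129515322 outside its lower end.

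Of the lists of growth and housekeeping genes, 5 carried Hdac1 in at least 2 lines more often than other genes, while oxidative phosphorylation genes did not. Hdac1 was at 18 of 22 immediate early genes (odds ratio 9.53, Fisher's exact test adjusted p = 4.07e-06), including Jund, Dusp2, Ier5 and Fosl2, at 37 of 56 translation initiation factor genes (odds ratio 4.47, adjusted p = 3.33e-07), including Eif5, Eif1a, Eif3a and Eif4e3, and at 23 of 39 cell cycle genes (odds ratio 3.30, adjusted p = 0.00102), including E2f1, E2f2, Ccne2 and Cdk6. It was at 47 of 83 ribosomal protein genes (odds ratio 3.03, Fisher's exact test adjusted p = 4.07e-06), including Rpl7, Rpl14, Rps19 and Rps25, and at 20 of 39 proteasome genes (odds ratio 2.44, adjusted p = 0.0182), including Psma7 and Psmc2. For Hdac2 in at least 2 lines none of these lists passed (5, 7, 4, 4 and 2 genes, adjusted p of 0.137, 0.801, 1, 0.164 and 0.574). In Bry alone Hdac2 was at 20, 34, 28, 39 and 21 of these genes (Fisher's exact test adjusted p of 4.79e-07, 0.000222, 1.97e-05, 0.0455 and 0.0397 over 120 tests). The ribosomal and proteasome Hdac1 calls were lost when a line was left out, with log2 odds ratios of -0.26 and -0.72 without Bry and -0.48 and -0.66 without Hd1_loxlox. The immediate early call was also lost, with log2 odds ratios of 1.49 without Bry and 1.28 without Hd1_loxlox against 3.25 (Fisher's exact test adjusted p of 0.126 and 0.159). In both settings a gene had to be in the Hd2lox Hdac1 list, which held 13 of 83 ribosomal, 4 of 39 proteasome and 10 of 22 immediate early genes. These losses therefore do not measure dependence on the omitted line. By library, these gene lists passed for Hdac1 in Bry and in Hd1_loxlox, and none was enriched in Hd2lox.

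Replication-dependent histone genes were depleted for Hdac1 (3 of 63, odds ratio 0.133, Fisher's exact test adjusted p = 4.07e-06) and for Hdac2 (0 of 63, adjusted p = 0.00439), although the Bry lists held 21 and 17 of them. The Hd1_loxlox Hdac2 list held 0 of the 63, and without it the Hdac2 depletion held (Fisher's exact test adjusted p = 0.00986). Hox genes were depleted for Hdac1 (2 of 39, odds ratio 0.154, Fisher's exact test adjusted p = 0.000642) and no Hdac2 depletion was detected in at least 2 lines (3 of 39, adjusted p = 0.882). By library, they were depleted for both antibodies in Bry (1 and 4 of 39, Fisher's exact test adjusted p of 3.87e-05 and 0.00299) and for Hdac1 in Hd1_loxlox (3 of 39, adjusted p = 0.00232), and neither Hd2lox list passed. Olfactory receptor genes, included as a negative control, had 0 of 1106 members for either antibody in at least 2 lines (and at most 7 in a single list), against 31.8% and 11.1% of other genes, with adjusted p of 4.95e-177 and 2.58e-54. The remaining lists did not pass for either antibody: cardiac, smooth muscle and mesenchymal genes (9 and 4 of 28), including Hand2 and Zeb1, pluripotency genes (5 and 2 of 17), including Klf2, neural and endoderm genes (5 and 3 of 16), including Sox1, oxidative phosphorylation genes (27 and 4 of 84), including Atp5a1, and Zfp genes (96 and 35 of 367), including Zfp24 and Zfp521. Their adjusted p lay between 0.164 and 1. The difference between the antibodies had an adjusted p of 0.75 or more in all 20 lists (exact permutation of the log2 odds ratios of 3 against 3 libraries), a test whose smallest unadjusted p is 0.1, so none could pass.

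**Figure D4:**
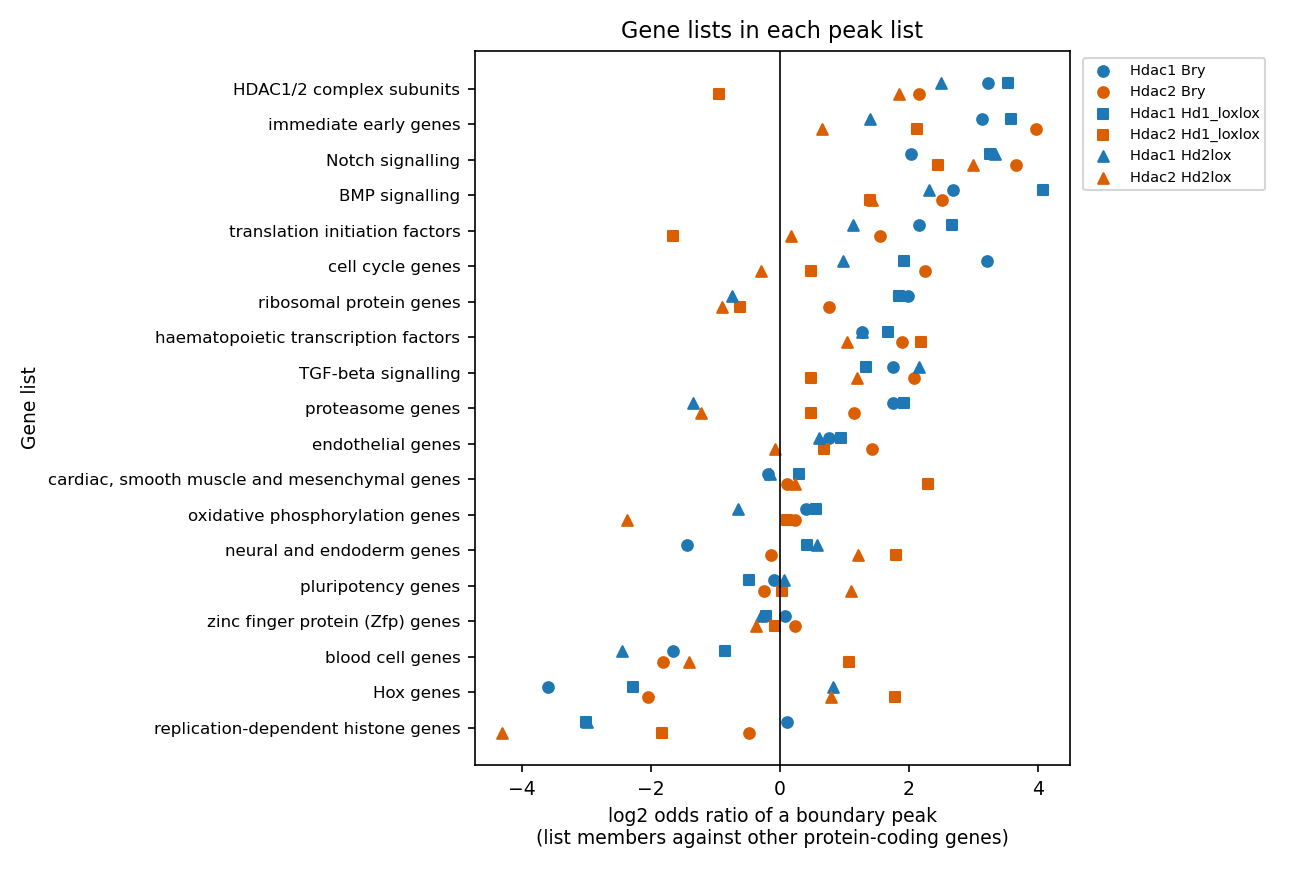
Log2 odds ratio of a peak at a gene end, list members against other protein-coding genes, for 19 gene lists (vertical axis) in the 6 peak lists, with colour for the antibody and marker shape for the line. Subunit genes of Hdac1 and Hdac2 complexes lie at 2.49 to 3.54 in the Hdac1 lists, and Hox and ribosomal protein genes separate Hd2lox Hdac1 (0.83 and -0.75) from the other Hdac1 lists.

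The last comparison was between the cell lines. The Hdac1 peak lists held ribosomal protein and Hox genes in different numbers by line. Ribosomal protein genes had Hdac1 at 54 of 83 members in Bry, 52 in Hd1_loxlox and 13 in Hd2lox. Hox genes had it at 1, 3 and 14 of 39. Each line had 1 Hdac1 library, so these differences between lines were not tested. In Hd2lox neither gene list passed for Hdac1 against other genes (Fisher's exact test adjusted p of 0.136 and 0.169). Both Hd2lox lists and no other list held an end peak at 377 genes. Hox genes made up 5 of the 18 with a peak in any list against 3.57% of other genes (odds ratio 11.01, Fisher's exact test adjusted p = 0.0138 over 80 tests). They were Hoxa4, Hoxb4, Hoxb9, Hoxc13 and Hoxd13, patterning genes of the body axis, named after their values were seen. Among the genes with the widest peaks in this set were the developmental transcription factors Nkx2-4, Foxe1, Foxd3 and Dmrta2, the cell cycle inhibitor Cdkn1c, and the neuronal genes Dlgap1 and Nexmif. At Dmrta2 the Hdac1 and Hdac2 peaks lay at opposite ends of the gene. Without Bry the set held 779 genes.

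Both Bry lists and the Hd1_loxlox Hdac1 list, with no Hd2lox list, held 1907 genes. Ribosomal protein genes made up 26 of 64 there against 18.1% of other genes (odds ratio 3.11, Fisher's exact test adjusted p = 0.00209), a call lost when each list was shortened to the length of the shortest by peak width (unadjusted p = 0.308). Genes of both Bry lists alone numbered 555 and included Kiss1r and Sspo, whose peaks lay outside the annotated genes, the adjacent histone genes H2ac8 and H2bc8, which shared a peak, Myh9, a non-muscle myosin, Tgif1, a TGF-beta co-repressor, Ddx6 and Mid1ip1. Both Hd1_loxlox lists alone shared 15 genes, among them Ptch1, the hedgehog receptor, Gfus, L3mbtl2, Grin2a, Sidt1, Vps35l and the adjacent Tmie and Als2cl. At Ptch1, L3mbtl2 and Vps35l the Hdac1 and Hdac2 peaks lay at opposite ends of the gene. These sets rest on peaks at gene ends, and peaks anywhere in Tgif1 were in 2 Hdac1 lists and 1 Hdac2 list. No other list passed in these 4 sets. With 1 library for each line and antibody, differences between lines have no replicate check.

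Chromosomes 8 and 11 carried more peaks in Bry and Hd1_loxlox than in Hd2lox. The share of chromosome 8 genes with an Hdac1 peak was 1.62 times that of the autosomes other than 8, 11 and 16 in Bry, 1.80 times in Hd1_loxlox and 1.24 times in Hd2lox. On chromosome 11 the ratios were 1.39, 1.82 and 1.15. For Hdac2 they were 1.62, 2.47 and 1.24 on chromosome 8 and 1.36, 2.70 and 1.02 on chromosome 11. Chromosome 16 stood out in Hd1_loxlox alone for Hdac1, at 1.44 against 1.06 in Bry and 1.014 in Hd2lox. Several genes named above lie there, among them Smad1, Jund and Ing2 on chromosome 8, Maml1 and Smurf2 on chromosome 11, and Hes1 on chromosome 16. Of the 10 genes with the widest Hdac1 peaks, Ing1, Zfp423, Sall1 and Irf2bp2 lie on chromosome 8 and Bahcc1 on chromosome 11. The others of the 10 lie on other chromosomes. Without chromosomes 8, 11, 16, X and Y fewer genes were tested and 4 calls were lost. The log2 odds ratio was 1.43 against 1.59 for haematopoietic transcription factors and 0.80 against 1.29 for proteasome genes with Hdac1 (Fisher's exact test adjusted p of 0.0873 and 0.269). With Hdac2 it was 1.78 against 1.83 for BMP signalling and 1.11 against 1.44 for complex subunits (Fisher's exact test adjusted p of 0.0827 and 0.302).

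**Figure D5:**
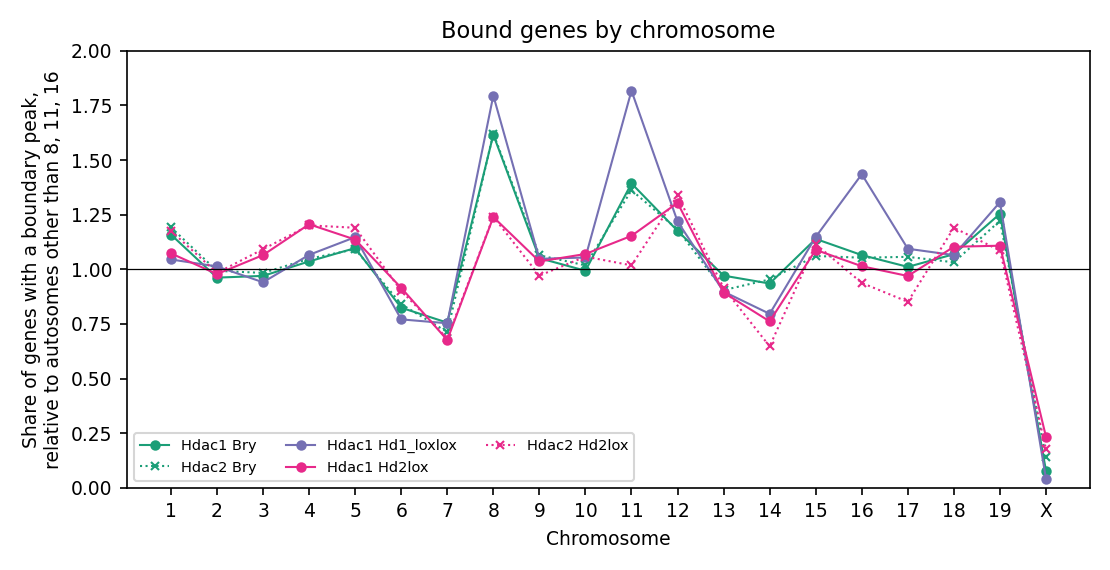
Share of protein-coding genes with a peak at an end on each chromosome, relative to the autosomes other than 8, 11 and 16 (vertical axis), for the 5 peak lists other than Hdac2 of Hd1_loxlox, with colour for the line, filled points and solid lines for Hdac1, and crosses and dotted lines for Hdac2. Chromosomes 8 and 11 reach 1.80 and 1.82 for Hdac1 in Hd1_loxlox, against 1.24 and 1.15 in Hd2lox.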

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

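The lines went opposite ways in the contrast of Hdac2 with Hdac1. Hdac2 had 1608 more peaks than Hdac1 in Bry and 1563 more in Hd2lox, whereas the difference in Hd1_loxlox was -2329. For genes with a peak at an end the difference was 543 in Bry, -6340 in Hd1_loxlox and -2369 in Hd2lox. These differences between lines were not tested, since each line and antibody has 1 library. The Hd2lox Hdac2 list held 5726 regions found in no other list, and 3.39% of these lay at gene ends. Random placement put 4.41% of the peaks of that list at gene ends. Whether such regions are background calls was not tested, so the larger Hd2lox count cannot be read as more Hdac2 binding. No formal test for outlying samples was run on groups of 3 libraries. The Hd1_loxlox Hdac2 list was singled out after the data were seen. Of the tests reported next, those of background calls, of Hdac2 at other sites, of gene density and of developmental families were chosen after the result was seen, and the others before.

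The Hd1_loxlox Hdac2 list shared few regions with any other list. Displaced coordinates are argued against, since a constant shift of up to 2 Mb gave over 1.5 times the unshifted overlap with the Hdac1 list of the same line on 1 autosome (chromosome 13) of 19, and unshifted overlap exceeded the matched random level in every pair. Background calls are a candidate explanation: the share of its peaks at gene ends was 2.12 times the random share, within a bound of 3 that was itself set after the data were seen, while the excess over random could come from true binding or from background gathering in open chromatin, which was not tested. Hdac2 bound at other sites in this line cannot be told apart from it, because the number of libraries of this line and antibody is 1. The peaks per Mb of the list on chromosomes 8, 11 and 16 were 3.41, 4.11 and 2.21 times those of the remaining autosomes. For Hdac1 in the same line the values were 1.99, 3.18 and 1.31. Which explanation this favours was not tested, since copy number was not measured. No count of regions or genes over all 3 Hdac2 lists should be read without the value that leaves this list out.

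Chromosomes 8 and 11 carried more Hdac1 peaks in Hd1_loxlox and Bry than in Hd2lox. A few clustered loci are argued against, since the ratio of Hd1_loxlox to Hd2lox, relative to the other autosomes, was 1.93 and stayed at 1.83 without the 2 bins of largest excess on each chromosome. The gene density of these chromosomes is argued against too, since the ratio of bound genes itself was 1.52 times as high in Hd1_loxlox as in Hd2lox. Extra copies of whole chromosomes 8 and 11 in part of the cells may account for the pattern, as a hypothesis: 100% of the 26 bins of 10 Mb had more Hd1_loxlox peaks than the other autosomes predict, against 38.1% of 218 bins of the autosomes other than 8, 11 and 16, while 92.3% of the 26 did in Bry, and chromosome 16 had 8 of 10 such bins in Hd1_loxlox (ratio 1.57). Copy number itself was not measured here, and a biological difference in binding between the lines stays open as untested.

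The genes bound in both Hd2lox lists and in no other list were enriched for Hox genes. Independent background spread at random over gene ends and other places is argued against, since their 647 shared regions were 2.59 times the highest of 100 matched random placements. Errors of a shared input would not be excluded by this. Background gathering in open chromatin in both lists would also exceed these placements and was not tested. Weak peaks near the calling threshold stay open: 29.7% of the genes kept a peak in both lists when each was reduced to its wider peaks, between the bounds set for either answer. A candidate explanation on the biological side is that Hdac1 and Hdac2 in this line occupy genes of developmental transcription factors as a class. Of 100 such genes of other families with a peak in any list, 15 were in this set against 3.50% of other genes (odds ratio 4.997, Fisher's exact test p = 2.66e-06), and the line cannot be told apart here from any batch it was handled in.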

How the results depend on the processing

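The wider 50%, equal-length, file-order, list-omission and chromosome-omission settings were chosen after seeing the data, the others before. Planned settings that rank by the authors' score, remove soft-masked repeats, match promoter CpG or concern motifs (with a GC-matched background) were not run. The share of Hdac1 peaks at gene ends exceeded that of Hdac2 in every setting run. Pairing by cell line leaves the differences of means (-280.7 peaks, 36.6 percentage points) unchanged by construction. The smallest p of its sign-flip permutation test is 0.25, so it could change no call and is no check of these results. Of list odds ratios under alternatives, 470 stayed on their side of the threshold (a change of sign counted only for those past it), 49 lost it, 14 gained it and 9 changed sign; of named genes, 1065 counts of lists with a peak were unchanged and 583 were not, by construction where a list was left out. Counts of regions, genes and lists that moved by over 1.5 times are given below. Fewer lists make counts over all lists rise by construction, and shorter lists make them fall; otherwise the cause was not tested.

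Leaving out each line, or the Hd1_loxlox Hdac2 list alone, the difference in peaks ranged from -1620.5 to 383 (lowest without the Hd1_loxlox Hdac2 list, reversed without Bry and, at 360.5, without Hd2lox), regions in all Hdac1 lists from 3214 to 5534, in all Hdac2 lists from 190.0 to 2283, Hdac1-only from 138 to 1759, Hdac2-only from 8 to 32, shared genes from 119 to 1642, enriched lists from 6 to 10 for Hdac1 and 0 to 4 for Hdac2, Hd2lox-only genes from 390.0 to 779, and genes of Bry and Hd1_loxlox from 1907 to 3120. The Jaccard difference by antibody ranged from -0.0851 (reversed, without Hd1_loxlox) to 0.0747. Without the Hd1_loxlox Hdac2 list alone there were 1464 shared genes. With the wider 50% of each list there were 41 Hdac2 regions, 0 Hdac2-only regions and 22 shared genes, with 1114 Hdac1 regions, 0 enriched Hdac2 lists and 856 genes of Bry and Hd1_loxlox. With equal lengths there were 1858 Hdac1 regions, 3 Hdac2-only regions, 57 shared genes, 2 enriched Hdac2 lists and 1046 genes of Bry and Hd1_loxlox. In file order the values were 1347 Hdac1 regions, 70.0 Hdac2 regions, 84 Hdac1-only and 2 Hdac2-only regions, 33 shared genes, 631 Hd2lox-only genes, 885 genes of Bry and Hd1_loxlox, and a Jaccard difference by antibody of -0.00632. Reciprocal overlap of 50% left 43 Hdac2 regions and 214 Hdac1-only regions. Windows of 2500 and 5000 bp gave 155 and 251 shared genes. Without chromosomes 8, 11, 16, X and Y there were 86 Hdac2 regions, 0 Hdac2-only regions and 2 enriched Hdac2 lists, and ends of all annotated genes gave 7. With a peak required in all 3 lines, 6 Hdac1 and 0 Hdac2 lists were enriched.

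The log2 odds ratios that changed sign were, with Hdac1, ribosomal protein genes (-0.26 without Bry, -0.48 without Hd1_loxlox, -0.25 in all 3 lines, up to 1.80 without Hd2lox) and proteasome genes (-0.72, -0.66 and -0.43, up to 1.63), and with Hdac2, complex subunits (-0.0154 without Hd2lox, up to 1.60 without Hd1_loxlox) and histone genes (-3.76 without Hd1_loxlox to 0.0879 without Bry, 0.37 in all 3 lines). Except without Hd1_loxlox, these Hdac2 sets had to be in the Hd1_loxlox Hdac2 list, which held no subunit and no histone gene, so their signs come from the 0.5 added to each cell and are no reversal; without that list both calls held. The negative Hdac1 values came from sets that had to be in the Hd2lox Hdac1 list. TGF-beta genes stayed enriched for Hdac1 in all settings run.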

Other observations

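The test over all distal regions was written before its result was seen, while its narrower forms, the reverse set of developmental families and the form of the Hdac2-only split count were chosen after. Haematopoietic transcription factor genes had Hdac1 regions away from gene ends nearby more often than other genes, although most of them had none. Of 6739 regions in at least 2 Hdac1 lists, 798 overlapped no end window of any annotated gene. Such a region lay within 50 kb of an end of 10 of 30 haematopoietic transcription factor genes (33.3%), against 8.50% of other protein-coding genes (odds ratio 5.51, Fisher's exact test p = 0.000122). The 10 genes were Tal1 (with 2 regions), Lyl1, Lmo2, Gfi1, Gfi1b, Gata2, Zfpm1, Ets1, Nfe2 and Ldb1. Tal1, Lyl1, Lmo2, Gata2 and Ldb1 encode members of a complex that drives early blood formation, and Gfi1 and Gfi1b encode repressors that silence the endothelial programme and recruit histone deacetylases. The region at Gata2 was at 88189108-88191449 on chromosome 6, at Gfi1b at 28597790-28600332 on chromosome 2, at Lmo2 at 103969110-103971268 on chromosome 2, and at Ldb1 at 46044263-46045933 on chromosome 19. At Tal1 (the first of its regions), Gfi1, Lmo2, Zfpm1, Ets1 and Ldb1 the region lay inside the gene. Among the genes that also had Hdac1 at an end the numbers were 5 of 17 against 11.6% (odds ratio 3.36, Fisher's exact test p = 0.0392).

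Regions outside all annotated genes numbered 114, and 3 of the 30 haematopoietic factors had such a region within 50 kb, against 1.13% of other genes (odds ratio 11.1, Fisher's exact test p = 0.00481). Of the other lists tested in the same way over all distal regions, TGF-beta genes had 8 of 39 (odds ratio 2.90, Fisher's exact test p = 0.0156), endothelial genes 6 of 34 (odds ratio 2.45, p = 0.0653) and Hox genes 0 of 39 (p = 0.0755). These p-values are not adjusted. As a hypothesis, Hdac1 in these cells may sit at enhancers of haematopoietic factors, which rests on the odds ratio of 5.51 and the narrower tests above, all of position alone. Promoters inside genes were not in the table used here, so a distal region can be an internal promoter, above all at the genes with a region inside.

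Splitting the 6 lists 3 against 3 in all 10 ways cannot give a share under 0.05. The real split gave 135 Hdac1-only and 1 Hdac2-only region, and 6 of the 10 splits gave at least as many on their larger side and 7 on their smaller side. The highest other values were 1772 and 21. The split with 1772, both Bry lists and the Hd1_loxlox Hdac1 list against the rest, gave several times the real count, which points to a structure of the lists other than the antibody, with the Bry lists apart from the Hd2lox lists and those of Hd1_loxlox divided.

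The genes of developmental transcription factor families with an end peak in both Hd2lox lists alone were Lhx2, Nkx2-1, Nkx2-2, Nkx6-1, Nkx6-2, Sox2, Sox3, Sox5, Foxe3, Dlx6, Gata2, Pou4f2, Tbx18, Six6 and Irx1. This holds for end peaks only, since peaks anywhere in Gata2 were in 3 Hdac1 lists and 2 Hdac2 lists. Among the genes of Bry and Hd1_loxlox without Hd2lox the same families were under-represented, with 7 of 100 against 18.4% (odds ratio 0.357, Fisher's exact test p = 0.00244). The genes just listed could not be in that set by definition, so this follows in part from the Hd2lox result and is no separate support. Chromosome X carried 25 and 63 peaks in Bry (Hdac1 and Hdac2), 17 and 2 in Hd1_loxlox, and 111 and 77 in Hd2lox. Chromosome Y carried 8 and 3, 8 and 4, and 0 and 0 peaks.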
